A study of Homo sapiens with 15 samples.

How the data were processed

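RNA sequencing of NTERA2 cells was read from the tables deposited for the whole series, which hold 15 libraries, 3 for each of 5 siRNAs. Cells were grown in medium with 10% serum and given siRNA 2 times over 7 days, and RNA was column purified, per the labels' protocols. Libraries were sequenced on a DNBSEQ instrument as paired 100 bp reads, per the labels' protocols. Reads were aligned with STAR to GRCh37, handled with SAMtools and counted with featureCounts, per the submitters' processing notes, with versions, annotation and strand setting not given in the sources used here. The raw counts per gene were deposited for 28207 gene symbols, and 3175 of these had no count in any library. The normalised table holds a signal of counts scaled per library, deposited for 20407 genes. For 20398 of these genes the deposited value was the count times 1 factor per library, to a tolerance of 1e-06. The reciprocal of that factor was 1.01 to 1.02 times the DESeq2 size factor. Genes left out of the normalised table had at most 32 counts over all libraries. Columns carry the group and no replicate number, so each column was used as a library of its group, numbered only to name it. No genome of the build used was at hand, so no coordinates are given. Reads from overlapping or antisense genes, and from near-identical copies such as histone and ribosomal protein genes and their pseudogenes, could be split differently by another counting, and values of these genes are uncertain.

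The library totals were 35275570 to 44996064 counts. Genes were kept by filterByExpr on the 5 groups, which left 18760, and scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) in 1 fit of all 15 libraries and 5 groups, with 10 residual degrees of freedom and no covariates. Each knockdown was compared with siControl, and siIGF2BP1 with each other knockdown. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM are counts scaled by the TMM-adjusted library size with edgeR's cpm function, given as mean ± SD of 3 libraries, and the log2 fold change is given ± its SE. The SD measures the spread between the libraries of a group. The SE comes from the joint fit, which pools the spread within all 5 groups. Whether either takes in separate cultures is not given. Principal components used log2 CPM with a prior count of 2. Libraries were compared in pairs by a chi-square test of their counts, divided by the number of genes with a summed count of at least 10.

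Before the data were examined, 28 gene lists were fixed, with 783 entries and 744 distinct symbols, of which 768 entries were found. The 15 mitochondrial genome transcripts were not found under their symbols and are not analysed here, and the 4 siRNA targets are described singly. The 26 tested lists were pluripotency, neural, mesoderm, endoderm, trophoblast and extraembryonic, HOX, SRF cytoskeletal, SRF immediate early, YAP/TEAD, FOXM1 and G2/M, G1/S and replication, p53 and IGF2BP1 target mRNA genes. They further held histones, ribosomal proteins, interferon, stress response, cholesterol, hypoxia and glycolysis, ERK output, WNT, TGF-beta with Nodal and BMP, epithelial with mesenchymal and matrix, fibroblast, blood and endothelial genes, and paralogs and partners of the targets. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists within a comparison, beside camera with an estimated correlation and fry. With an estimated correlation 1 list in siIGF2BP1 (IGF2BP1 target mRNAs) and 2 in siSRF (these and pluripotency) passed. With it 0 passed in siFOXM1 and 0 in siIQGAP3, where 5 and 2 lists had an unadjusted p under 0.05 and fry called 6 and 8.

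The rule for named genes was also fixed before the data were examined. It takes the siRNA targets and their paralogs and partners. It takes the 10 largest increases and the 10 largest decreases among genes past the threshold, with a mean of at least 5 CPM in 1 of the 2 groups and every knockdown library beyond every control library. It takes up to 4 members of each list with the smallest p-values past the threshold, or up to 2 members with the highest expression where none passed. For genes shared by all 4 knockdowns it takes the 10 highest and the 10 lowest, and for direct comparisons the 5 largest in each direction. Other genes are named as members of a list, or with the statement that they were chosen after their values were seen.

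The correlation and overlap of comparisons that share the 3 controls were set beside 50 simulations of unchanged groups against the same controls. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, limma-trend on the normalised values with a pseudocount of 1, size factors and library size in place of TMM, other filters, only the 2 groups compared, and each library left out in turn. Added after seeing the data were column order as a block, libraries 1 and 2 of each group summed with all 3 of siIQGAP3 taken as 1, the third libraries of the groups left out, siIQGAP3 against the third siControl library alone (camera with either correlation), and the 9 genes on which the tables disagree taken from the normalised table or left out. Also added then were camera with an estimated correlation in every refit, and the lists of the direct comparisons with 1 library left out, with the block and with the third libraries left out. The test was tried on simulated counts of 18165 genes, made from the siControl means with set changes put into siIGF2BP1. Genes and libraries were drawn independently, without the grouping of the real libraries. The test recovered 23 of 100 genes changed by a log2 of 1 and 94 of 100 changed by 3, called 8 unchanged genes, and called 0 in a comparison with no change. On the same simulation camera gave a shifted list an adjusted p of 3.30e-33 and an unchanged list 0.655. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Levels of XIST and of Y-linked genes are not reported.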

Results

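NTERA2 is an established human embryonal carcinoma line, a tumour-derived line that expresses pluripotency genes. RNA was sequenced from NTERA2 cells given siRNA 2 times over 7 days. The 5 groups of 3 libraries received a control siRNA (siControl) or an siRNA against IGF2BP1, SRF, FOXM1 or IQGAP3. IGF2BP1 is an oncofetal protein that binds mRNA. SRF is a transcription factor of cytoskeletal and immediate early genes, FOXM1 is a transcription factor of G2/M genes, and IQGAP3 is a scaffold protein of the IQGAP family. The series concerns how IGF2BP1 bears on IQGAP3 and on stem cell properties. Each library held 35275570 to 44996064 counts over 28207 genes, and 18760 genes were tested. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of a group are numbered 1 to 3 only to name them.

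The libraries of a group did not always lie together. On the first principal component of log2 CPM (counts scaled by library size), which held 62.8% of the variance, the third siControl library scored 131 and the siIQGAP3 libraries 157. The other siControl libraries scored -51.4 and -75.8, and those of the other 3 knockdowns -85.0 to -10.3. The chi-square per gene between siControl libraries 1 and 2 was 16.9, against 451 and 558 between each of them and the third. In siIGF2BP1, siSRF and siFOXM1 the third library also stood apart, at 124 to 267 against 2.28 to 4.48 between libraries 1 and 2. The siIQGAP3 libraries differed from each other by 1.82 to 4.40. Fits with the third libraries left out therefore rest on the spread between near-alike libraries, which may be technical. LHX9, a LIM homeobox gene, was at 478 and 529 CPM in siControl libraries 1 and 2 and at 0.0213 in the third. HOTTIP, a long non-coding RNA next to the HOXA genes, was at 145 and 173 CPM in those libraries and at 0.0427 in the third. Both genes were chosen after their values were seen.

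**Figure D1:**
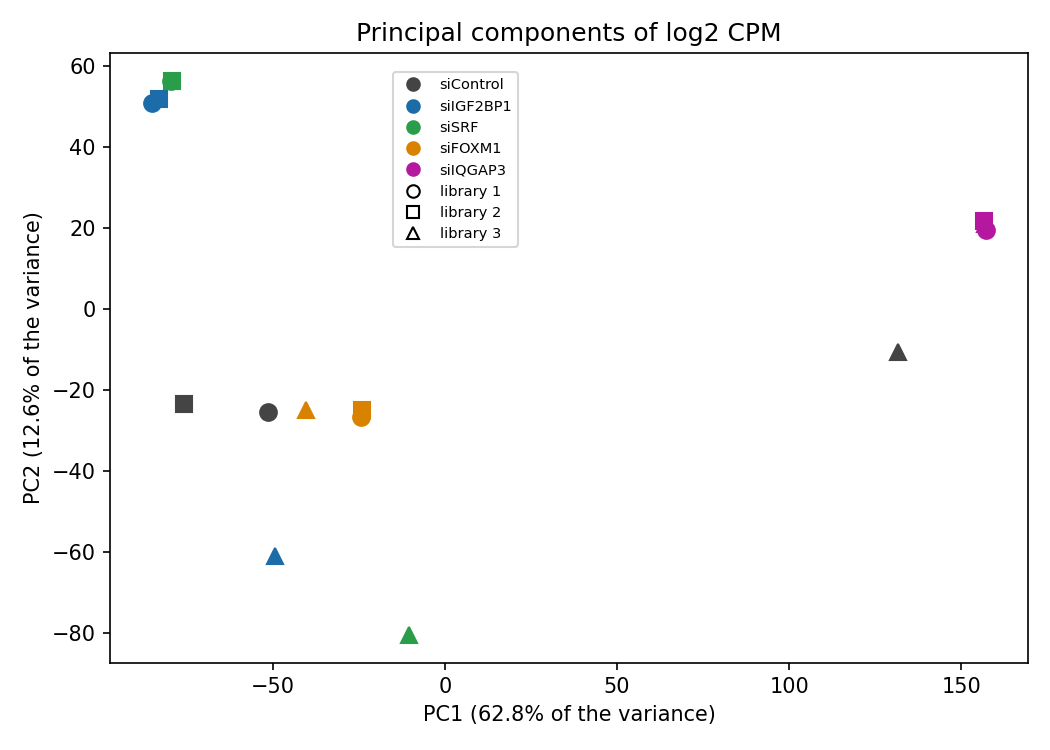
Scores of the 15 libraries on the first 2 principal components of log2 CPM, with colour for the siRNA and shape for the library number within its group. The siIQGAP3 libraries (157) and the third siControl library (131) lie at one end of the first component, which holds 62.8% of the variance.

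The deposited counts and the deposited normalised values disagree on a few genes. For 20398 of the 20407 genes in both tables, the normalised value was the count times 1 factor per library (tolerance 1e-06). The 9 others were IGF2BP1, SRF, FOXM1, IQGAP3, POU5F1, NANOG, KLF4, MYC and A1BG, with 73 of 299827 entries off by -29.1% to 21.5%. Of those 73 differences, 25 were multiples of 10 to within 0.001, where chance would give 0.0146, and each of the 9 genes had at least 1. In the third siControl library the normalised value was 5000 above the count times the factor for both IGF2BP1 and FOXM1. In the same units POU5F1 was 5900 above it, SRF 650 and NANOG 500. For SRF, 3 entries corresponded to counts with 1 decimal, 315.1, 284.6 and 272.1. Counts that are not whole were not particular to these 3, as with 266.16 for SRF in siSRF library 1. All tests used the counts, and no call on a target or named gene changed when the normalised values of the 9 genes were used in their place. Departures of this size are small beside most of the changes called, so the exchange could hardly alter a call. It does not show that the values are right. Values of these genes rest on tables that disagree.

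Each siRNA lowered its own target, in counts on which the tables disagree. IGF2BP1 fell in siIGF2BP1 from 879 ± 139.7 to 183 ± 26.0 CPM (mean ± SD, n = 3), a log2 fold change of -2.26 ± 0.16 (SE; adjusted p = 5.23e-05). SRF fell in siSRF (log2 fold change -3.73 ± 0.17, adjusted p = 3.09e-07) and FOXM1 fell in siFOXM1 (-2.28 ± 0.28, adjusted p = 0.00199). IQGAP3 fell in siIQGAP3 to 48.0% of the control level, 50.2 ± 1.67 against 105 ± 22.0 CPM, a log2 fold change of -1.06 ± 0.28 (adjusted p = 0.0138). Against the third siControl library alone it was -0.72 (adjusted p = 0.244). The IQGAP3 call was also lost without siControl library 2 (-0.90, adjusted p = 0.0596) and without siIQGAP3 library 3 (-1.04, adjusted p = 0.0504).

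The other targets moved in a nested order, again in counts on which the tables disagree. The counts themselves are uncertain, since IGF2BP1 had the highest chi-square of 18711 genes between siFOXM1 libraries 1 and 2 (1253, median 0.822). In siIGF2BP1, SRF fell to 7.97% of control (log2 fold change -3.65 ± 0.17), FOXM1 to 30% (-1.73 ± 0.27) and IQGAP3 to 17.9% (-2.48 ± 0.30), with adjusted p = 3.90e-07, 0.00773 and 0.00137. In siSRF, FOXM1 fell to 29.3% and IQGAP3 to 19.7% of control (adjusted p = 0.00569 and 0.00179), and IGF2BP1 did not pass the test (-0.31 ± 0.16, adjusted p = 0.400). In siFOXM1, IQGAP3 fell to 6.70% of control (adjusted p = 1.05e-04), with IGF2BP1 at 0.08 ± 0.16 and SRF at 0.09 ± 0.15 (adjusted p = 0.929 and 0.911). In siIQGAP3, IGF2BP1 was at -0.14, SRF at 0.12 and FOXM1 at -0.11, none of which passed (adjusted p = 0.499, 0.552 and 0.764). With the third libraries left out, IGF2BP1 in siSRF, SRF in siFOXM1, and IGF2BP1 and FOXM1 in siIQGAP3 shifted further, as given below. None of the 11 paralogs and partners of the targets passed in siIGF2BP1, siSRF or siFOXM1, IGF2BP2, IGF2BP3 and IQGAP1 among them. In siIQGAP3 MRTFA, an SRF coactivator, fell (-0.38 ± 0.13, adjusted p = 0.0452; -0.04 against the third siControl library alone, adjusted p = 0.890), but not without siControl library 1 or 2 (adjusted p = 0.125 and 0.220) or siIQGAP3 library 1, 2 or 3 (0.0971, 0.104 and 0.141). IQGAP3 was lower in siIGF2BP1 (18.7 ± 4.40 CPM) and siFOXM1 (7.01 ± 2.29 CPM) than in siIQGAP3 itself by these group means.

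**Figure D2:**
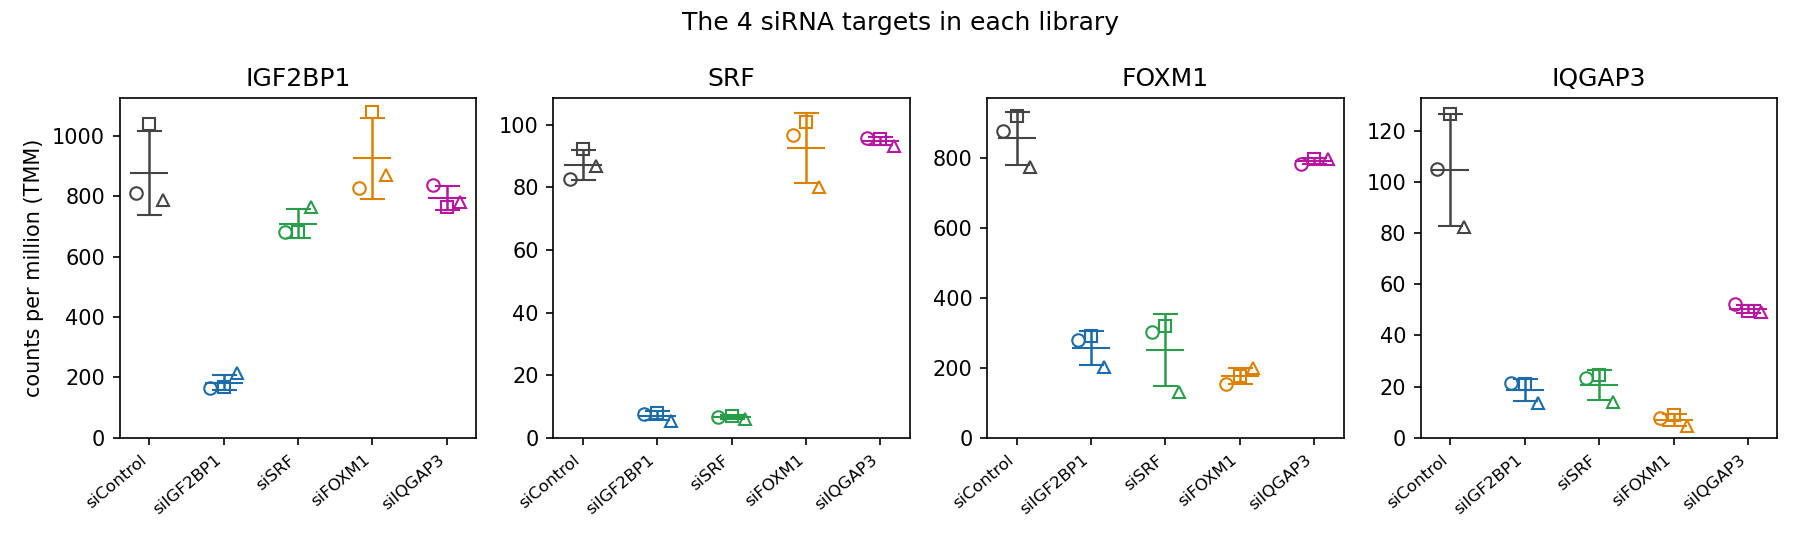
CPM (TMM-scaled) of IGF2BP1, SRF, FOXM1 and IQGAP3 in each library, with a bar for the mean and SD of 3 libraries per group. IQGAP3 averaged 105 CPM in siControl and 50.2 CPM in siIQGAP3, and all 4 genes are among those on which the deposited tables disagree.

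Knockdown of IGF2BP1 asks which genes depend on this RNA-binding protein. Some pluripotency and Nodal pathway genes were among those that fell in siIGF2BP1. PRDM14, a transcription factor of pluripotent and germ cells, fell from 27.2 ± 11.5 to 1.22 ± 0.402 CPM (log2 fold change -4.48 ± 0.35, adjusted p = 7.81e-05). NODAL, a TGF-beta family ligand, and its antagonist LEFTY1 fell (log2 fold change -4.02 and -4.21, adjusted p = 0.00357 and 0.00106). CDH1, which encodes E-cadherin, fell from 165 ± 113 to 8.10 ± 6.78 CPM. Complement factor I (CFI) rose from 0.365 ± 0.273 to 32.6 ± 9.15 CPM (log2 fold change 6.50 ± 0.56, adjusted p = 1.01e-04), and DHRS3, a retinaldehyde reductase, rose from 11.2 ± 2.62 to 119 ± 64.2 CPM.

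Of the 30 pluripotency genes, 12 fell and none rose in siIGF2BP1, and 20 fell when adjusted over the list alone. The list was lower by camera (adjusted p = 8.36e-31; adjusted p = 0.0509 with an estimated correlation). NANOG, POU5F1 and KLF4 were among those that fell (-4.78, -4.24 and -3.44), on tables that disagree, and without the 9 genes 9 members of the list still fell (adjusted p = 1.50e-19; adjusted p = 0.213 with an estimated correlation). The 12 became 6, 6 and 7 without siIGF2BP1 library 1, 2 or 3, and 22 with 4 higher when the third libraries were left out. The list median of -2.60 was -1.57 without the third siControl library and -1.45 with the third libraries left out. Of 39 HOX genes, 3 rose and none fell, and 8 rose when adjusted over the list alone (adjusted p = 2.51e-15; adjusted p = 0.170 with an estimated correlation). The 3 became 1 and 5 without siControl library 1 or 3, 1 without siIGF2BP1 library 1 or 2, and 23 with 3 lower when the third libraries were left out. HOXB4 reached 4.87 ± 2 CPM against 0.215 ± 0.170, HOXA5 29.5 ± 3.48 against 2.78 ± 2.08 and HOXB3 21.1 ± 6.31 against 2.64 ± 1.23. HOXA5 lost its call without siIGF2BP1 library 1 or 2 (adjusted p = 0.0652 and 0.0724), HOXB4 without siControl library 1 (0.0503), and HOXB3 without any 1 of these 3 (0.0504, 0.0550 and 0.0513). CYP26B1, which degrades retinoic acid, rose from 4.69 ± 0.196 to 341 ± 273 CPM, with 451, 541 and 30.3 CPM in the 3 libraries. Its call was lost without siIGF2BP1 library 1 or 2 and without siControl library 1, 2 or 3 (adjusted p = 0.103, 0.103, 0.0964, 0.0553 and 0.0626).

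The TGF-beta, Nodal and BMP list had 5 of 23 members lower in siIGF2BP1, NODAL and LEFTY1 among them, and 7 when adjusted over the list alone (adjusted p = 0.00237; adjusted p = 0.170 with an estimated correlation). The epithelial, mesenchymal and matrix list had 5 of 36 lower, including CDH1 and CLDN4, a tight junction claudin (-2.71), and 7 when adjusted over the list alone (adjusted p = 5.18e-04; adjusted p = 0.372 with an estimated correlation). SRF and TAGLN2 were the 2 of 39 SRF cytoskeletal targets that fell, and 3 fell when adjusted over the list alone. That list was lower by camera (adjusted p = 3.77e-07; adjusted p = 0.334 with an estimated correlation). TAGLN2 lost its call without any 1 of 5 of the 6 libraries, with adjusted p = 0.0555 and 0.0511 without siControl library 1 or 3, and 0.211, 0.148 and 0.124 without siIGF2BP1 library 1, 2 or 3. With column order as a block it did not pass either (adjusted p = 0.0756). SRF, MYC and FOXM1 were the 3 of 33 literature IGF2BP1 target mRNAs that fell, also 3 when adjusted over the list alone (adjusted p = 1.50e-05; adjusted p = 0.00810 with an estimated correlation). All 3 are genes on which the tables disagree, and without the 9 genes the list did not pass (adjusted p = 0.275; adjusted p = 0.492 with an estimated correlation). VWF and CDH5 fell in the blood and endothelial list (2 of 10, and 4 when adjusted over the list alone; adjusted p = 0.00698; adjusted p = 0.0920 with an estimated correlation). CDH5 lost its call without siIGF2BP1 library 1 or 2 (adjusted p = 0.101 and 0.0854).

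Smaller shifts called by camera in siIGF2BP1 were lower ERK output (0.00237), hypoxia and glycolysis (0.0231) and G2/M genes (0.0182), as adjusted p. With an estimated correlation their adjusted p = 0.447, 0.451 and 0.774. Higher lists were stress response genes (1.42e-04), ribosomal proteins (1.29e-06), p53 targets (0.0200) and histones (0.0334), with adjusted p = 0.334, 0.570, 0.570 and 0.401 with an estimated correlation. Without the third siControl library the G2/M, ribosomal and histone lists did not pass (adjusted p = 0.174, 0.533 and 0.0837). Without siIGF2BP1 library 3 the G2/M, hypoxia and p53 lists did not pass (adjusted p = 0.899, 0.326 and 0.249). The hypoxia and p53 lists were also lost without siControl library 1 (0.0794 and 0.0714) or 2 (0.318 and 0.120). The histone list was lost without siControl library 2 (0.0571) or siIGF2BP1 library 1 or 2 (0.108 and 0.108). With the third libraries left out the stress list (0.944), ribosomal proteins (0.165), p53 targets (0.0572) and blood and endothelial genes (0.131) did not pass, and G2/M genes were higher without passing (0.574). Without the 9 genes the ERK list did not pass (adjusted p = 0.105), its only called member being MYC. The remaining lists did not pass. Their adjusted p values were 0.357 for paralogs and partners, 0.966 for neural, 0.204 for mesoderm, 0.292 for endoderm and 0.234 for trophoblast genes. SRF immediate early (0.292), YAP/TEAD (0.104), G1/S (0.105), interferon (0.966), cholesterol (0.343), WNT (0.268) and fibroblast genes (0.675) did not pass either. G1/S genes were higher with the third libraries left out, and SRF immediate early, cholesterol and fibroblast genes lower (adjusted p = 1.20e-07, 0.0130, 0.0101 and 0.0308). G1/S genes were lower without siControl library 1 or 2 (0.0263 and 0.0217) or siIGF2BP1 library 1 or 2 (0.00188 and 0.00384). Cholesterol genes were higher without siControl library 1 or 2 (0.0267 and 0.0217) and lower without the third (7.30e-05), as were SRF immediate early genes (0.0383). YAP/TEAD genes were lower without siControl library 1 or siIGF2BP1 library 3 (0.0383 and 0.0488), and mesoderm genes higher without the latter (0.0488). None of these passed in its setting with an estimated correlation (adjusted p = 0.113 to 0.758). In total 303 genes changed in siIGF2BP1, 54 higher and 249 lower, with 43 and 230 of these at an absolute log2 fold change of at least 1. The count was 157, 581 and 520 without siControl library 1, 2 or 3, and 67, 76 and 191 without siIGF2BP1 library 1, 2 or 3. It was 4 with only the 2 groups in the fit, 0 by edgeR with libraries 1 and 2 summed (941 at an unadjusted p under 0.05), 1113 by DESeq2 and 9505 with the third libraries left out. Summed, all 38 named genes lost their calls, and with the third libraries left out all 38 kept them. Libraries 1 and 2 of siIGF2BP1 had a chi-square per gene of 4.48, against 124 and 136 to the third. The fit without the third libraries may thus measure technical spread only, and calls kept there add little support.

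Many of the genes named for siIGF2BP1 also changed in siSRF. PRDM14 (log2 fold change -4.33 ± 0.35, adjusted p = 9.83e-05), LEFTY1 (-4.41) and NODAL (-3.57) fell. DNMT3L, a cofactor of DNA methyltransferases, fell from 8.31 ± 5.67 to 0.186 ± 0.0858 CPM. CDH1 fell from 165 ± 113 to 6.51 ± 2.66 CPM (log2 fold change -4.66 ± 0.63, adjusted p = 0.00263). CFI rose to 42.9 ± 15.1 CPM and HOXB4 from 0.215 ± 0.170 to 8.92 ± 8.52 CPM (log2 fold change 5.38 ± 0.76, adjusted p = 0.00351). CNR1, a cannabinoid receptor, rose by a log2 fold change of 4.67 ± 0.63 (adjusted p = 0.00263).

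Of the 30 pluripotency genes, 11 fell and none rose in siSRF, and 20 fell when adjusted over the list alone. This list remained lower with an estimated correlation (adjusted p = 1.23e-32, and adjusted p = 0.0386 with an estimated correlation), but not without the 9 genes (adjusted p = 0.181 with an estimated correlation, 1.03e-20 with the preset one), when 8 of its members fell. It was not called with an estimated correlation without the third siControl library (0.1001) or with the third libraries left out (0.136). The 11 became 6 without siSRF library 1 or 2, and 22 with 4 higher when the third libraries were left out. The list median of -2.57 was -1.47 without the third siControl library and -1.28 with the third libraries left out. Of 39 HOX genes, 5 rose, and 10 when adjusted over the list alone (adjusted p = 6.31e-17; adjusted p = 0.136 with an estimated correlation). The 5 became 3 and 9 without siControl library 1 or 3, and 23 with 6 lower when the third libraries were left out. They included HOXB3 (3.70), HOXA5 (3.97) and HOXB2 (3.96), the last of which did not pass without siControl library 1 (adjusted p = 0.0769). SRF itself fell among the 39 SRF cytoskeletal targets, 1 over all genes and 1 when adjusted over the list alone, and the list was lower by camera (median log2 fold change -0.35, adjusted p = 2.95e-06; adjusted p = 0.309 with an estimated correlation). Of these targets 3 fell without the third siControl library (median -0.16), and with the third libraries left out 28 fell and 5 rose. The list median was -0.18 and -0.19 without siSRF library 1 or 2 and -0.63 without the third. None of the 20 SRF immediate early targets passed over all genes, 2 fell and 1 rose without the third siControl library, and 16 fell and 1 rose with the third libraries left out. EGR1 was at -0.86 ± 0.86 (adjusted p = 0.724). That list was lower by camera (adjusted p = 0.0440; adjusted p = 0.372 with an estimated correlation), but not without the 9 genes (adjusted p = 0.0508), siControl library 1 or 2 (0.135 and 0.344) or siSRF library 3 (0.201). The epithelial list had 3 of 36 members lower, CDH1, CLDN4 and EPCAM, and 7 when adjusted over the list alone (adjusted p = 3.29e-04; adjusted p = 0.309 with an estimated correlation). EPCAM did not pass without siSRF library 1 or 2 (adjusted p = 0.137 and 0.139). IGF2BP1 target mRNAs had SRF, MYC and FOXM1 lower (3 of 33, and 4 when adjusted over the list alone; adjusted p = 6.70e-06, and 0.00581 with an estimated correlation), and did not pass without the 9 genes (adjusted p = 0.281; adjusted p = 0.403 with an estimated correlation).

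Stress-induced SESN2, in both the p53 and the stress response list, rose by a log2 fold change of 0.91 ± 0.12 (adjusted p = 0.00259), 1 of 43 and 1 of 30 members. Among p53 targets 4 rose without the third siControl library (2 without the second or with column order as a block), when 6 stress genes rose and 1 fell. The p53 list had 16 higher and 8 lower and the stress list 10 and 10 with the third libraries left out. The p53 list was higher (adjusted p = 2.25e-04; adjusted p = 0.323 with an estimated correlation), as was the stress list (3.29e-04; 0.309 with an estimated correlation), the latter not without the third siControl library (adjusted p = 0.179). Histone genes were higher (adjusted p = 0.00388; adjusted p = 0.278 with an estimated correlation). Lower lists were Nodal and BMP targets (0.0137), hypoxia (0.00355), G2/M (3.02e-04), G1/S (0.0195), ERK output (0.0156) and blood and endothelial genes (0.00388), as adjusted p. With an estimated correlation their adjusted p = 0.299, 0.309, 0.715, 0.817, 0.508 and 0.0705. The lower G1/S and G2/M calls reversed with the third libraries left out, when both lists were higher in siSRF (adjusted p = 3.85e-12 and 0.0200). Without siSRF library 3 alone G1/S genes were higher (adjusted p = 0.0242), and the G2/M, hypoxia and p53 lists did not pass (adjusted p = 0.201, 0.167 and 0.397). Without the third siControl library the Nodal, G1/S and ERK lists did not pass (adjusted p = 0.0654, 0.842 and 0.249). The ERK list was also lost without siSRF library 1 or 2 (0.203 and 0.214) and without the 9 genes (0.345), and the hypoxia list without siControl library 2 (0.122). With the third libraries left out the p53 (0.106), stress (0.817), Nodal (0.0893) and blood and endothelial lists (0.152) did not pass. Other lists were called only in other settings. Cholesterol and ribosomal genes were lower without the third siControl library (1.71e-11 and 0.00238) and interferon genes higher (0.0362). Ribosomal genes were higher without siControl library 1 or 2 or siSRF library 3 (0.00177, 2.38e-04 and 0.0142). Without siSRF library 3 mesoderm genes were higher (0.0248) and YAP/TEAD targets lower (0.0218), and with the third libraries left out cholesterol (9.05e-08) and fibroblast genes (0.0292) were lower. None of these, nor the reversed G1/S and G2/M lists, passed there with an estimated correlation (adjusted p = 0.0541 to 0.807). In total 294 genes changed, 69 higher and 225 lower. The count was 158, 446 and 1273 without siControl library 1, 2 or 3, and 104, 103 and 461 without siSRF library 1, 2 or 3. It was 1 with only the 2 groups in the fit, 0 by edgeR with libraries 1 and 2 summed (844 at an unadjusted p under 0.05), 1130 by DESeq2 and 10446 with the third libraries left out.

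G2/M genes, which FOXM1 is known to activate, changed little singly in siFOXM1. Of 57 FOXM1 and G2/M genes, KIF14, a mitotic kinesin, fell (log2 fold change -0.92 ± 0.20, adjusted p = 0.0457), and 3 fell when adjusted over the list alone. The list median was -0.37 (adjusted p = 2.77e-08; adjusted p = 0.626 with an estimated correlation). TOP2A was at -0.71 ± 0.26 and did not pass. KIF14 did not pass without siControl library 1 or without siFOXM1 library 1, 2 or 3 (adjusted p = 0.126, 0.151, 0.187 and 0.0834), nor with column order as a block (0.0539). The larger changes were elsewhere. HOXB4 rose from 0.215 ± 0.170 to 16.8 ± 5.78 CPM (log2 fold change 6.30 ± 0.79, adjusted p = 0.00212), and DUSP6, a phosphatase of ERK, from 4.13 ± 0.620 to 93.9 ± 69.7 CPM (4.51 ± 0.68, adjusted p = 0.00709). ATP12A, a proton pump subunit, fell from 21.2 ± 8.37 to 1 ± 0.0380 CPM (-4.40 ± 0.36, adjusted p = 1.05e-04).

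Of the 30 pluripotency genes, 8 fell and none rose in siFOXM1, and 16 fell when adjusted over the list alone (adjusted p = 8.61e-26; adjusted p = 0.0755 with an estimated correlation), with 5 lower without the 9 genes (adjusted p = 9.04e-15; adjusted p = 0.254 with an estimated correlation). The 8 became 5 without siFOXM1 library 1 or 2, and 16 with 7 higher when the third libraries were left out. The list median of -1.64 was -0.65 without the third siControl library and -0.36 with the third libraries left out. PRDM14 (-4.09) and LEFTY1 (-3.25) were among them. Of 39 HOX genes, 6 rose, and 10 when adjusted over the list alone, HOXA5 (4.11) and HOXB3 (3.86) among them (adjusted p = 2.73e-19; adjusted p = 0.109 with an estimated correlation). The HOX median of 1.104 was 0.16 with the third libraries left out, when 16 rose and 15 fell, and 3 rose without siControl library 1. Hypoxia and glycolysis genes were lower, with none of 29 past the threshold over all genes and 7 lower and 1 higher when adjusted over the list alone (adjusted p = 2.51e-07; adjusted p = 0.109 with an estimated correlation). Unfolded protein and integrated stress response genes were higher, ATF3 alone passing over all genes (0.72 ± 0.14), and 5 higher and 1 lower when adjusted over the list alone (adjusted p = 6.86e-07; adjusted p = 0.203 with an estimated correlation). ATF3 did not pass without any 1 of siControl libraries 1 and 2 and the siFOXM1 libraries (adjusted p = 0.0536 to 0.126). Interferon response genes were higher, with OASL past the threshold and 8 when adjusted over the list alone (adjusted p = 1.84e-05; adjusted p = 0.447 with an estimated correlation). OASL was at 0.848, 0.497 and 18.2 CPM in the 3 siFOXM1 libraries, and without the third of them the list did not pass (adjusted p = 0.0934). OASL itself did not pass without siControl library 1 or 2 (adjusted p = 0.137 and 0.0906) or with column order as a block (0.0683). The SRF cytoskeletal list did not pass in siFOXM1 (adjusted p = 0.693), and was higher without siFOXM1 library 3 (adjusted p = 0.00325; adjusted p = 0.585 with an estimated correlation) and with the third libraries left out (2.25e-08; 0.0494 with an estimated correlation).

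Further lists called in siFOXM1 were lower G1/S genes (3.13e-05), IGF2BP1 target mRNAs (0.00268) and epithelial genes (0.0233), as adjusted p. Higher ones were ribosomal proteins (1.05e-05), p53 targets (0.00126) and mesoderm genes (0.0265). With an estimated correlation their adjusted p = 0.704, 0.0755, 0.626, 0.679, 0.515 and 0.447. Without the third siControl library the G1/S, ribosomal and mesoderm lists did not pass (adjusted p = 0.540, 0.790 and 0.790). Without siFOXM1 library 3 the IGF2BP1 target, epithelial and p53 lists did not pass (adjusted p = 0.103, 0.103 and 0.112). Without the 9 genes, which include MYC and FOXM1 as its called members, the IGF2BP1 target list did not pass (adjusted p = 0.427). The epithelial list was also lost without siControl library 1 (0.0800) and the mesoderm list without siFOXM1 library 2 (0.0562). With the third libraries left out the G1/S (0.111), ribosomal (0.941), mesoderm (0.202) and epithelial lists (0.124) did not pass. The epithelial genes included CDH1 (-4.59), and the only mesoderm gene past the threshold, HAND1, fell (-3.22) in a list whose median was 0.46. HAND1 did not pass without siControl library 1 or 2 or any siFOXM1 library (adjusted p = 0.0596 to 0.175). Lists called only in other settings included cholesterol genes, lower without the third siControl library (1.62e-06) and higher without the second (0.0470). Nodal and BMP targets were lower without siControl library 2 (0.0144) or siFOXM1 library 1 or 2 (0.0367 and 0.0277), and blood and endothelial genes without siFOXM1 library 1 (0.0487). YAP/TEAD, ERK and neural genes were higher with the third libraries left out (0.00210, 9.48e-04 and 0.0265) and cholesterol genes lower (0.00375). None of these passed there with an estimated correlation (adjusted p = 0.0625 to 0.733). In total 210 genes changed, 54 higher and 156 lower. The count was 69 and 1548 without siControl library 1 or 3, and 68 and 71 without siFOXM1 library 1 or 2. It was 7 with only the 2 groups in the fit, 0 by edgeR with libraries 1 and 2 summed (676 at an unadjusted p under 0.05), 863 by DESeq2 and 10237 with the third libraries left out.

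The comparison of siIQGAP3 with siControl gave the most calls, 6096 genes with 2034 higher and 4062 lower. Here the third siControl library stood with the siIQGAP3 libraries. Values of named genes, and some values of lists, are therefore followed by those against the third siControl library alone. That is a single library assumed to vary like the groups. Its chi-square per gene to the siIQGAP3 libraries was 118 to 121. Libraries 1 and 2 of siIGF2BP1, siSRF and siFOXM1 differed from the third of the same siRNA by 124 to 267. Differences against the third siControl library may thus be no more than differences between libraries. Some WNT pathway targets were among the genes that fell. NOTUM, which inactivates WNT proteins, fell from 93.4 ± 31.2 to 1.74 ± 0.420 CPM (log2 fold change -5.75 ± 0.44, adjusted p = 1.44e-05; -5.06 against the third library, adjusted p = 3.41e-05). RNF43, a ubiquitin ligase that removes WNT receptors, was at -3.75 (-4.22 against the third library, adjusted p = 1.75e-04) and AXIN2 at -2.37 (-1.81, adjusted p = 0.00170). CDX2, a caudal homeobox factor, fell too (-5.84, and -6.66 against the third library, adjusted p = 6.07e-04), as did TFAP2A (-4.76, and -2.57, adjusted p = 1.10e-05). The forebrain transcription factor OTX2 rose by 5.30 (4.78 against the third library, adjusted p = 0.0275), and SIX3 from 0.0603 ± 0.0444 to 11.7 ± 0.699 CPM (adjusted p = 0.0327 against the third library).

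Of 19 WNT targets, 10 fell and 1 rose in siIQGAP3, and 12 fell when adjusted over the list alone (adjusted p = 2.48e-05; adjusted p = 0.495 with an estimated correlation). Against the third siControl library alone 10 fell and 4 rose (adjusted p = 2.06e-04; adjusted p = 0.424 with an estimated correlation). Of 43 p53 targets, 14 rose and 4 fell, and 17 rose when adjusted over the list alone (adjusted p = 3.99e-04; adjusted p = 0.717 with an estimated correlation; adjusted p = 9.01e-04 against the third library, and 0.812 there with an estimated correlation). TRIAP1 rose by 1.31 (0.77 against the third library, adjusted p = 0.0463), and FDXR fell (-0.86, and -0.50 against the third library, adjusted p = 0.0432). Of 21 ERK output genes, 7 rose and 2 fell, and 9 rose when adjusted over the list alone (adjusted p = 0.00171; adjusted p = 0.717 with an estimated correlation; adjusted p = 0.106 against the third library). DUSP4 rose from 2 ± 0.984 to 63.3 ± 1.27 CPM and DUSP6 from 4.13 ± 0.620 to 96.6 ± 1.49 CPM (4.33 and 4.66 against the third library). SPRY2, an ERK feedback inhibitor, rose by 1.16 (1.18).

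The pluripotency list split in siIQGAP3, with 7 of 30 higher and 6 lower, 8 and 6 when adjusted over the list alone, and no call by camera (adjusted p = 0.218). TERF1, a telomere-binding protein, rose by 1.35 (1.70 against the third library) and ZFP42, a pluripotency marker chosen after its value was seen, from 0.0162 ± 0.0143 to 1.87 ± 0.364 CPM (adjusted p = 0.0866 against the third library). LEFTY1 and NODAL fell, at -3.06 and -3.27 (-3.83 and -4.18 against the third library). POU5F1, NANOG and KLF4 fell too, at -3.80, -3.38 and -4.57 (-3.57, -3.12 and -3.93), on tables that disagree, and without the 9 genes the list was higher in siIQGAP3 (adjusted p = 0.00338; adjusted p = 0.611 with an estimated correlation). It was also higher with the third libraries of the other groups left out (adjusted p = 0.00891; adjusted p = 0.513 with an estimated correlation). Other genes on the list ran against these 3 in siControl: SOX2 was at 59.3, 35.7 and 176 CPM and L1TD1 at 27.1, 13.5 and 157 CPM in libraries 1 to 3, both chosen after their values were seen. NANOGP8, a copy of NANOG, averaged 4.56 CPM in siControl libraries 1 and 2, with 14.7 in the third and 13.5 in siIQGAP3. The POU5F1 copies POU5F1P3 and POU5F1P4 were at 0.434 and 0.245 CPM in siControl libraries 1 and 2 and 1.59 and 1.09 in siIQGAP3. These values are near the floor, and POU5F1B did not rise (1.79 and 1.41). The copies were also chosen after their values were seen, and the fall of POU5F1 and NANOG in siIQGAP3 stays uncertain.

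**Figure D3:**
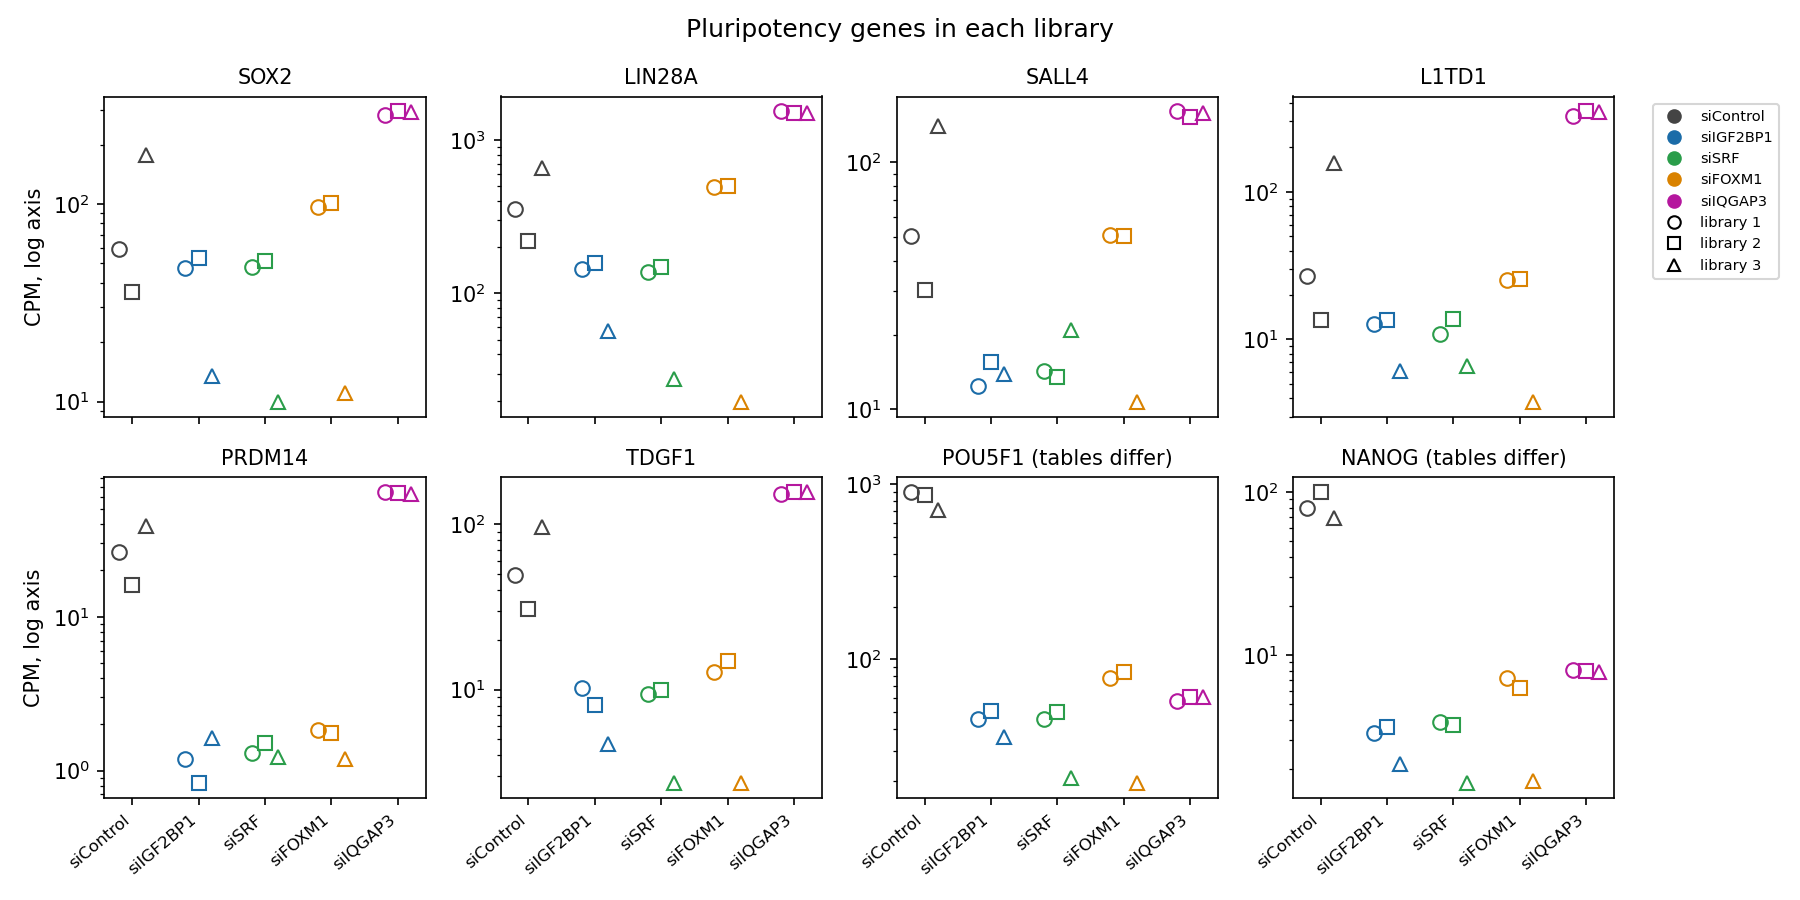
CPM on a log axis of 8 pluripotency genes in each library, with colour for the siRNA and shape for the library number. SOX2 reached 176 CPM in the third siControl library against 59.3 and 35.7 in the other two, and POU5F1 and NANOG are genes on which the deposited tables disagree.

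Other lists in siIQGAP3 depended on which controls were used. Of 39 HOX genes 24 fell and 2 rose, 25 and 4 when adjusted over the list alone (adjusted p = 9.27e-04; adjusted p = 0.717 with an estimated correlation), and against the third library 9 rose and 5 fell (adjusted p = 0.188). HOXA13 averaged 0.0650 ± 0.0153 against 87.9 ± 76.1 CPM, and the third library had 0.107 CPM (adjusted p = 0.663 against it). HOXC13 was at -4.36 (-2.79, adjusted p = 1.09e-04). Of 57 ribosomal protein genes 19 fell, also 19 when adjusted over the list alone (adjusted p = 5.09e-04; adjusted p = 0.719 with an estimated correlation), RPL12 at -1.34 (-0.30, adjusted p = 0.167). Against the third library 2 ribosomal genes rose and the list did not pass (adjusted p = 0.106). Stress response genes fell (15 of 30, and 15 when adjusted over the list alone; adjusted p = 0.0129; adjusted p = 0.717 with an estimated correlation; 0.474 against the third library), as did hypoxia genes (12 of 29 with 1 higher, and 13 when adjusted over the list alone; 0.0129; 0.717 with an estimated correlation; 0.0992 against the third library). SRF cytoskeletal targets were higher (5 of 39 rose and 1 fell, and 2 rose when adjusted over the list alone; adjusted p = 0.00800; adjusted p = 0.717 with an estimated correlation; 0.141 against the third library). YAP/TEAD targets were higher (4 of 22 rose and 2 fell, also 4 and 2 when adjusted over the list alone; adjusted p = 0.0194; adjusted p = 0.717 with an estimated correlation; 0.202 against the third library). Fibroblast markers did not pass against all 3 controls (adjusted p = 0.446), and 5 of 12 rose against the third library (adjusted p = 3.61e-07; adjusted p = 0.0480 with an estimated correlation). The collagen COL3A1 was at 1726 ± 1498 CPM in siControl and 121 ± 2.42 in siIQGAP3, -3.83 against all 3 controls and 5.10 against the third alone, and did not pass with column order as a block (adjusted p = 0.0501). Without the third siControl library fibroblast (0.00130), epithelial (0.0125) and mesoderm genes (0.0132) were lower and G1/S genes higher (0.0241). Without siControl library 1 or 2 trophoblast genes were lower (0.0264 and 0.0221) and cholesterol genes higher (0.0206 and 0.00860), and with column order as a block interferon genes were higher (0.00982). The epithelial list was also lower with the third libraries of the other groups left out (adjusted p = 0.00141; adjusted p = 0.0458 with an estimated correlation). Fibroblast, mesoderm, SRF immediate early and trophoblast genes were then lower (2.30e-07, 0.00437, 0.00437 and 0.00983), and G1/S, interferon and neural genes higher (0.00437, 0.00596 and 0.0249). None of the others passed there with an estimated correlation (adjusted p = 0.0571 to 0.872).

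Against the third siControl library alone 2373 genes changed in siIQGAP3, 836 higher and 1537 lower, and 1599 were among the 6096, of which 1519 changed in the same direction. Every siIQGAP3 library lay beyond every siControl library for 9062 of the 18760 genes (48.3%), where chance gives 10%, and for 5025 of the 6096. The count was 10711 without the third siControl library, of which 5952 were among the 6096. It was 3690 and 3519 without siControl library 1 or 2, and 3898, 3874 and 3818 without siIQGAP3 library 1, 2 or 3. It was 3619 with only the 2 groups in the fit, 0 by edgeR with libraries 1 and 2 of the other groups and all 3 siIQGAP3 libraries summed (1531 at an unadjusted p under 0.05), 7170 by DESeq2 and 15500 with the third libraries of the other groups left out.

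**Figure D4:**
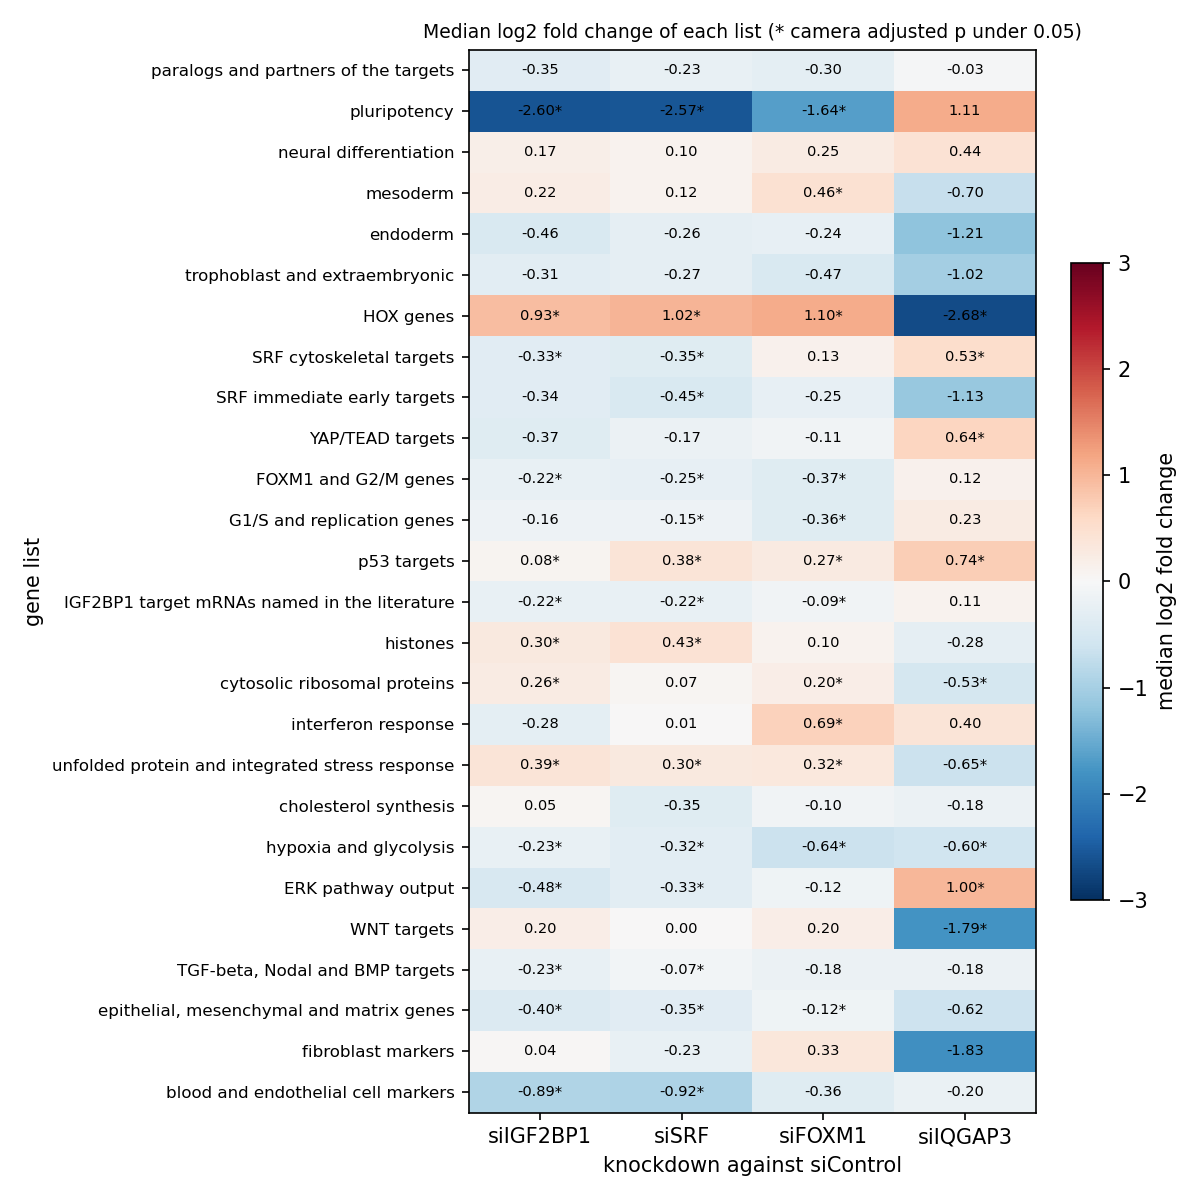
Median log2 fold change of the 26 tested gene lists in each knockdown against siControl, with an asterisk where camera with its preset correlation gave an adjusted p under 0.05. Pluripotency genes have medians of -2.60, -2.57 and -1.64 in siIGF2BP1, siSRF and siFOXM1 (-1.45, -1.28 and -0.36 with the third libraries left out), and WNT targets -1.79 in siIQGAP3.

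The 4 comparisons with siControl were set against each other across genes, which are not independent replicates. The log2 fold changes of siIGF2BP1 and siSRF had a Pearson correlation of 0.917, those of siIGF2BP1 and siFOXM1 0.758, and those of siSRF and siFOXM1 0.796. Unchanged groups simulated against the same 3 controls gave 0.504 ± 0.0103. The covariances were 0.788, 0.571 and 0.577, against a simulated 0.153. With the third libraries left out the correlation of siIGF2BP1 and siSRF was 0.928, and those of siFOXM1 with siIGF2BP1 and siSRF were 0.495 and 0.497, for which no unchanged groups were simulated. The simulation also takes libraries as independent, whereas libraries of the same column order deviated alike from their group means in siIGF2BP1 and siSRF (correlations 0.711 to 0.868) and less so in siControl and these 2 groups (0.112 to 0.318). Part of the excess may come from that and from the shared controls, which are too few to split. With siIQGAP3 the correlations were -0.0605 for siIGF2BP1, 0.0804 for siSRF and 0.175 for siFOXM1, and the covariances -0.0912, 0.117 and 0.223. Without the third siControl library these 3 correlations were 0.330, 0.461 and 0.559, and without siSRF library 3 that of siSRF was -0.0536. That of siFOXM1 was 0.0793 without siControl library 2. siIGF2BP1 and siSRF shared 44 higher and 181 lower genes, where independent lists would share 0.199 and 2.99. That value takes no account of the shared controls, and the simulated unchanged groups, which shared 0, hold no change to call, so neither tells a shared effect from shared controls. The shared genes numbered 17 and 103, 43 and 347 and 213 and 272 without siControl library 1, 2 or 3, 8 and 56 and 9 and 64 without siIGF2BP1 library 1 or 2, and 3743 and 4838 with the third libraries left out. They numbered 21 and 73, 22 and 70 and 68 and 233 without siSRF library 1, 2 or 3, 26 and 127, 28 and 134 and 92 and 318 without siFOXM1 library 1, 2 or 3, and 24 and 117, 26 and 118 and 26 and 117 without siIQGAP3 library 1, 2 or 3.

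Genes changed the same way in all 4 knockdowns numbered 15 higher and 72 lower, and 24 and 109 in siIGF2BP1, siSRF and siFOXM1. CFI rose in all 4, by log2 fold changes of 6.50, 6.90, 5.87 and 5.74. CNR1 rose by 3.91, 4.67, 4.99 and 2.60. DHRS3 and HOXA5 were also among the 15. RBBP8NL, DNMT3L and VTCN1, the immune checkpoint protein B7-H4, fell in all 4. VTCN1 was at -4.84, -5.24, -4.50 and -3.61. ATP12A and TMPRSS13, a membrane serine protease, were at -4.20 and -5.37 in siIGF2BP1 and -4.94 and -4.60 in siIQGAP3. POU5F1, MYC, NANOG and KLF4 were among the 72 on tables that disagree. NANOGP8, the copy of NANOG, was higher in siIQGAP3 (13.5 CPM) than in siControl (7.95 ± 5.91). The 87 genes shared by all 4 became 311 without the third siControl library and 42 without siControl library 1. They numbered 42 and 44 without siFOXM1 library 1 or 2, 44 and 51 without siIGF2BP1 library 1 or 2, 55 without siSRF library 1 or 2, and 53, 52 and 52 without siIQGAP3 library 1, 2 or 3. The 133 shared by siIGF2BP1, siSRF and siFOXM1 became 58 and 401 without siControl library 1 or 3, 60 and 68 without siIGF2BP1 library 1 or 2, and 77 and 75 without siSRF library 1 or 2. They numbered 58 and 59 without siFOXM1 library 1 or 2, and 85, 80 and 85 without siIQGAP3 library 1, 2 or 3.

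Direct comparisons of the knockdowns do not use the control means, though the controls enter the estimate of spread in the joint fit. Between siIGF2BP1 and siSRF 1 gene differed by edgeR, IGF2BP1 (log2 fold change -1.96 ± 0.16, adjusted p = 5.21e-04), with 53 genes at an unadjusted p under 0.05. Libraries of the same column order in siIGF2BP1 and siSRF deviated alike from their group means (correlations across genes 0.722, 0.711 and 0.868), which the fit ignores. With column order as a block 1 gene again differed, with 58 at an unadjusted p under 0.05. With only these 2 groups in the fit 0 differed by edgeR, with 184 at an unadjusted p under 0.05 and 2 genes by DESeq2 on all libraries. Camera called 5 lists between siIGF2BP1 and siSRF, with no member of any past the threshold and adjusted p = 0.840 for each with an estimated correlation. Ribosomal protein (median 0.19, adjusted p = 2.41e-17), cholesterol (0.27, 2.86e-08), G2/M (0.00653) and SRF immediate early genes (0.0413) were higher in siIGF2BP1, and p53 targets lower (0.00184). Without siSRF library 3 the G2/M genes were lower (5.69e-19) and p53 targets higher (0.0306), the cholesterol and immediate early lists did not pass (0.515 and 0.451), and the ribosomal median was 0.12. Without siIGF2BP1 library 1 or 2 the G2/M (0.808 and 0.709), immediate early (0.322 and 0.670) and p53 lists (0.152 and 0.128) did not pass. The immediate early list was also lost without siSRF library 1 (0.0556). G2/M genes were lower with the third libraries left out (7.93e-12; 0.0464 with an estimated correlation) and the p53 list did not pass (0.822). Between siIGF2BP1 and siFOXM1 the 2 genes that differed were SRF (-3.74, adjusted p = 3.06e-07) and IGF2BP1 (-2.34, adjusted p = 3.65e-05), and 206 differed without siFOXM1 library 3. DESeq2 called 64, and with the third libraries left out 10309 differed here and 339 between siIGF2BP1 and siSRF. SRF cytoskeletal targets were lower in siIGF2BP1 than in siFOXM1, with 1 of 39 past the threshold and 2 when adjusted over the list alone (adjusted p = 4.67e-16; adjusted p = 0.347 with an estimated correlation). Interferon genes were lower too, with 0 of 34 past the threshold by edgeR and 8 when adjusted over the list alone (median -1.096, adjusted p = 4.76e-09; adjusted p = 0.376 with an estimated correlation). Without siFOXM1 library 3, in which IFIT1 and OASL were high, they did not pass (median -0.29, adjusted p = 0.271), and with the third libraries left out the median was -0.27 (adjusted p = 0.0200). ERK output was lower in siIGF2BP1 (3.66e-04; 0.441 with an estimated correlation), and kept its call without any 1 library, as SRF cytoskeletal targets did. Pluripotency (0.00226) and YAP/TEAD genes (0.0492) were lower, and G2/M (3.76e-04), G1/S (0.00508), hypoxia (0.00143) and histone genes (0.0492) higher (adjusted p = 0.441 to 0.820 with an estimated correlation). The pluripotency list did not pass without siIGF2BP1 library 3 (0.175) or siFOXM1 library 1 or 2 (0.0712 and 0.0811). Without siFOXM1 library 3 the G2/M (0.183), G1/S (0.0652) and hypoxia lists (0.253) did not pass. The G2/M list was also lost without siIGF2BP1 library 1 (0.108) and the G1/S list without siIGF2BP1 library 1 or 2 (0.456 and 0.285). The YAP/TEAD and histone lists were lost without siIGF2BP1 library 1 or 2 or any siFOXM1 library (0.0712 to 0.189 and 0.0532 to 0.224).

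Between siIGF2BP1 and siIQGAP3 9367 genes differed, 5245 higher and 4122 lower in siIGF2BP1, and 12192 with only these 2 groups in the fit. The cancer-testis antigens CTAG2 and MAGEA10 were at 149 ± 36.8 and 35.3 ± 3.22 CPM in siIGF2BP1 and had no count in siIQGAP3. HOTTIP was at 136 ± 4.83 CPM against no count. DPPA3, a germ cell and pluripotency gene, was at 0.0168 ± 0.0145 CPM in siIGF2BP1 and 7.45 ± 0.223 in siIQGAP3, and MYL1, a muscle myosin light chain, at 0.0783 ± 0.0484 and 9.25 ± 1.44. Of the pluripotency genes 23 of 30 were lower and 1 higher in siIGF2BP1, also 23 and 1 when adjusted over the list alone (adjusted p = 4.46e-10; adjusted p = 0.322 with an estimated correlation). Of the HOX genes 30 of 39 were higher, also 30 when adjusted over the list alone (adjusted p = 2.91e-10; adjusted p = 0.322 with an estimated correlation). SRF cytoskeletal, YAP/TEAD, ERK and IGF2BP1 target genes were also lower in siIGF2BP1 (2.43e-06, 0.00608, 1.78e-05 and 0.00881), and ribosomal, stress and WNT genes higher (5.48e-08, 5.31e-05 and 1.66e-05), with adjusted p = 0.193 to 0.559 with an estimated correlation. G2/M genes were lower (0.0441; 0.771 with an estimated correlation), but not without siIGF2BP1 library 3 (0.287) or siIQGAP3 library 2 or 3 (0.0559 and 0.0545), with column order as a block (0.0590) or with the third libraries left out (0.207). The third siControl library, which received no siRNA against IQGAP3, had CPM near those of siIQGAP3 for HOTTIP (0.0427) and LHX9 (0.0213).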

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

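The alternatives to leave out the third libraries, sum libraries 1 and 2, set column order as a block, test siIQGAP3 against the third siControl library alone, replace or leave out the 9 genes on which the tables disagree, and repeat camera with an estimated correlation in these settings were chosen after seeing the data. Of 656 alternative values of 35 results, 519 kept their side of the threshold or their size, and 0 of the levels that passed the test changed direction. With 1 library left out, the correlations of siIQGAP3 with siIGF2BP1 and siSRF and the level of IGF2BP1 in siFOXM1, which did not pass, crossed 0. The values that kept their side or size were 189 of 246 with 1 library left out, 224 of 251 with the other settings fixed before the data were examined, and with the added ones 106 of 159. No paired analysis was possible by recorded replicate because the columns carry no replicate numbers. The planned replicate block was not run for that reason. Column order, which is an assumed and not a recorded pairing, was set as a block instead and gave 286 genes in siIGF2BP1 and 306 in siSRF. Named genes that then did not pass were CLUL1, LEFTY2, LCMT1-AS2, CER1, TAGLN2 (-1.09) and SLC2A1 in siIGF2BP1, LCMT1-AS2, TBXT and CER1 in siSRF, OASL, MMP11 and KIF14 (-0.92) in siFOXM1, and COL3A1 (-3.76) and COL1A2 in siIQGAP3. The cause of the changes below was not tested, apart from fewer libraries where libraries were left out or summed. Size factors or library size moved the median of all genes by under 0.06 (log2).

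With 1 library left out, the genes called ranged over 67 to 581 in siIGF2BP1, 103 to 1273 in siSRF, 68 to 1548 in siFOXM1 and 3519 to 10711 in siIQGAP3, and over 2 to 206 between siIGF2BP1 and siFOXM1. IQGAP3 in siIQGAP3 ranged over -1.21 to -0.90. Genes shared by all 4 knockdowns ranged over 42 to 311 and by siIGF2BP1, siSRF and siFOXM1 over 58 to 401. The correlations ranged over 0.774 to 0.933 for siIGF2BP1 with siSRF, 0.585 to 0.816 with siFOXM1 and -0.0797 to 0.330 with siIQGAP3. They ranged over 0.578 to 0.844 for siSRF with siFOXM1, -0.0536 to 0.461 with siIQGAP3, and 0.0793 to 0.559 for siFOXM1 with siIQGAP3.

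With only the 2 groups compared in the fit, edgeR called 4, 1, 7 and 3619 genes in siIGF2BP1, siSRF, siFOXM1 and siIQGAP3, and 0 between siIGF2BP1 and siSRF (184 at an unadjusted p under 0.05; 2 by DESeq2). IGF2BP1, FOXM1 and IQGAP3 in siIGF2BP1 were then at -2.27, -1.74 and -2.49, and FOXM1 and IQGAP3 in siSRF at -1.77 and -2.34. DESeq2 called 1113, 1130 and 863 genes in siIGF2BP1, siSRF and siFOXM1, 2 between siIGF2BP1 and siSRF and 64 between siIGF2BP1 and siFOXM1. At an absolute log2 fold change of at least 1, 3961 genes passed in siIQGAP3. With no filter the correlations with siSRF and siFOXM1 were 0.781 and 0.663 for siIGF2BP1, 0.680 between siSRF and siFOXM1, and 0.118 for siFOXM1 with siIQGAP3. Camera with an estimated correlation called 1, 2, 0 and 0 lists, and fry 6, 7, 6 and 8. With an estimated correlation it called 0, 0, 0 and 0 without the 9 genes, 3, 1, 0 and 1 without the third siControl library, and 6, 5, 2 and 5 with the third libraries left out.

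With the third libraries left out, 9505, 10446, 10237 and 15500 genes passed in siIGF2BP1, siSRF, siFOXM1 and siIQGAP3, and 339, 10309 and 15553 between siIGF2BP1 and siSRF, siFOXM1 and siIQGAP3. The libraries kept in a group were near-alike, so these counts may rest on technical spread only. IGF2BP1 in siSRF was then at -0.49, SRF in siFOXM1 at 0.16, and IGF2BP1 and FOXM1 in siIQGAP3 at -0.26 and -0.22. The correlations of siFOXM1 with siIGF2BP1 and siSRF were then 0.495 and 0.497, and those of siIQGAP3 with siIGF2BP1, siSRF and siFOXM1 0.196, 0.231 and 0.542, shared genes 3304 and 4443, and lists called in siIQGAP3 18. With libraries 1 and 2 of the other groups and all 3 of siIQGAP3 summed to leave 9 libraries, edgeR called 0 genes in each comparison, with 941, 844, 676, 1531, 16, 97 and 3144 at an unadjusted p under 0.05, and shared genes 0 and 0. IGF2BP1, SRF, FOXM1 and IQGAP3 were then at -2.16, -3.73, -1.78 and -2.51 in siIGF2BP1, SRF, FOXM1 and IQGAP3 at -3.79, -1.94 and -2.41 in siSRF, FOXM1 and IQGAP3 at -2.22 and -3.98 in siFOXM1, and IQGAP3 at -1.02 in siIQGAP3. Against the third siControl library alone 2373 genes passed in siIQGAP3 and IQGAP3 was at -0.72. Camera with an estimated correlation then called 2 lists. Genes named as lower in siIQGAP3 that were then higher were NEUROD1 (3.32), FOXA1 (0.89), FOXF2 (0.40), DSCC1 (0.11), H1-2 (0.18), DDIT4 (0.22), SQLE (1.61), INHBE (1.02), DCN (7.08), FAP (2.20), COL3A1 (5.10) and COL1A2 (1.54).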

Other observations

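The splits of the libraries and the comparisons with all 3 controls were fixed before the data were examined, and the other tests in this part were chosen after the results were seen. Cholesterol synthesis genes differed between siIQGAP3 and the third siControl library alone, with 15 of 25 higher, none lower and a median log2 fold change of 1.46 (adjusted p by camera = 8.57e-22; adjusted p = 0.174 with an estimated correlation). CYP51A1, a sterol demethylase, rose by 1.66 there (adjusted p = 7.06e-04), and by 1.35 ± 0.17 against all 3 controls. SQLE, squalene epoxidase, was at -2.53 against all 3 controls and at 1.61 against the third alone (adjusted p = 0.00236). Trophoblast and extraembryonic genes were lower against the third library (5 of 16, adjusted p = 3.06e-04; adjusted p = 0.0471 with an estimated correlation), WNT6 and GATA2 among them (-2.85 and -1.74), and neural genes higher (4 higher and 3 lower, adjusted p = 0.0204; adjusted p = 0.0942 with an estimated correlation).

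IFIT1, CYP26B1 and LEFTY2 had unlike levels in libraries of the same siRNA. IFIT1, an interferon-induced gene chosen after its values were seen, was at 6.20 and 5.88 CPM in siFOXM1 libraries 1 and 2 and at 137 in the third, against 4.45 to 8.51 in the other groups. CYP26B1 was at 316, 371 and 27.7 CPM in the siFOXM1 libraries and 464, 475 and 43.6 in the siSRF libraries, against 4.48 to 4.87 in siControl and 5.15 to 5.46 in siIQGAP3. LEFTY2 was at 61.7, 62.3 and 1.22 CPM in siFOXM1 and at 28.3, 16.8 and 32.8 in siControl.

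With 3 libraries against 3 there are 10 splits, so no share can be under 0.1 and the design is too small for this test to exclude chance. With only the 6 libraries in the fit, the real split called 4 genes in siIGF2BP1, 1 in siSRF, 7 in siFOXM1 and 3619 in siIQGAP3, and the highest other split called 0, 0, 2 and 0, so that 1 split was as large in each. Between siIGF2BP1 and siSRF all 10 splits called 0 by edgeR, where 184 genes had an unadjusted p under 0.05 in the real one and DESeq2 called 2. Between siIGF2BP1 and siIQGAP3 the real split called 12192 and the highest other 0, so 1 was as large. Between siIGF2BP1 and siFOXM1 the real split called 3, and 2 splits were as large. The other was that of siIGF2BP1 libraries 1 and 2 with siFOXM1 library 3 against the rest, which called 176 genes and points to a structure of the libraries.

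For the 9 genes on which the deposited tables disagree, 25 of the 73 differences are round, which argues against another set of read counts behind the normalised table for those entries. The genes being of interest to the study remains open: 8 of the 9 are among the 720 listed genes present in both tables (exact hypergeometric test, p = 2.02e-11), a pattern consistent with their entries having been handled apart from those of other genes. POU5F1 and NANOG had ratios of siControl library 2 to library 1 of 0.964 and 1.25. Both lay above the 0.498 to 0.893 of 19 other pluripotency genes chosen as at least 2 times higher in the third siControl library. Over all 25 others of at least 1 CPM the ratio reached 1.02 (POLR3G), with 0 as high as NANOG and 1 as high as POU5F1. This argues against NANOG following the others in these libraries, and leaves it open for POU5F1. IGF2BP1 had the highest chi-square of 18711 genes between siFOXM1 libraries 1 and 2, 1253 against a median of 0.822. Which step made these entries is not given in the sources used here, and values of these 9 genes in both tables stay uncertain.

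The siIQGAP3 libraries and the third siControl library stood apart from the other 11. Of 266 genes at least 10-fold apart between siIQGAP3 and the other 3 knockdowns, 235 (88.3%) had the third siControl library on the siIQGAP3 side, against 9 and 3 for siControl libraries 1 and 2, which argues against loss of IQGAP3 as the cause of those differences. IQGAP3 itself was lower in siIGF2BP1 (18.7 CPM), siSRF (20.6) and siFOXM1 (7.01) than in siIQGAP3 (50.2). Those 3 knockdowns lacked the siIQGAP3 levels of the 266 genes, though the IQGAP3 counts are ones on which the tables disagree. A grouping of libraries or cultures apart from the siRNA stays open, since the highest chi-square per gene between the third siControl library and a siIQGAP3 library was 121, against 451 and 558 to its own group. Cells of another kind in a varying share also stay open. The 179 genes high in the third siControl library and siIQGAP3 had ratios of siControl library 2 to 1 with a median of 0.640 and quartiles 1.33 times apart. For all genes of at least 5 CPM in both, the median was 1.01 and the quartiles 0.925 and 1.11. These are no wider apart, so the spread of the 179 does not mark a common share. A graded change of all cells could give the same. Effects of the siRNA within that grouping remain untested beyond the comparison with the third siControl library alone. Libraries of the same siRNA differed by as much (124 to 267), so that comparison cannot tell such effects from differences between libraries.

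The pluripotency list was lower in siIGF2BP1, siSRF and siFOXM1 by camera with its preset correlation (adjusted p = 0.0509, 0.0386 and 0.0755 with an estimated correlation), and a control group in which the third library is high could give that. Against siControl libraries 1 and 2, with all 3 libraries of each knockdown, the list's 27 other members had medians of -1.28, -1.32 and -0.58. In the same fit 177 genes high in the third siControl library and siIQGAP3 had 0.82, 1.39 and 1.88. The list's median was at percentile 0.01 of 10000 random sets of those genes in each of the 3 knockdowns, the smallest that so many sets can give. Those genes were chosen in these data as low in siControl libraries 1 and 2, and the list was not. A higher median for them is partly built in, so the percentile cannot decide on a share of cells like the third siControl library. Without the 9 genes the highest adjusted p of the list over the 3 knockdowns was 9.04e-15 with the preset correlation, so those genes are not the whole of that call. With an estimated correlation it was 0.254, and the list passed in none of the 3. Knockdown of the 3 targets stays open as a hypothesis, as do a share of such cells and a difference between cultures that the labels do not record.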
